A study of Mus musculus with 20 samples.

How the data were processed

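The series holds 20 libraries of polyadenylated mouse RNA (strain C57BL/6), made with a Smart-Seq kit from cells sorted by flow cytometry. Per the labels' protocols, tumour cells were gated as CD45-positive, CD11b-positive, Ly6C-negative and Ly6G-negative and split by the Flt3-Cre mTmG reporter, which marks cells of bone marrow origin in green. The protocols in the labels describe tumour generation for the GEMM, and how GL261 tumours were made is not given in the sources used here.

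The values are the deposited raw counts per gene symbol, whole numbers whose totals differ between libraries, so they show no normalization by the authors. The submitters' processing notes name CASAVA 1.8, STAR 2.5.0e, HTSeq, DESeq2 and the build mm10 without their role or order, and the annotation and strand setting of the counting are not given in the sources used here. Genes that overlap on opposite strands, and near-identical copies such as the Ly6, H2, S100, Chi3l3, Sirpb1 and Tgtp genes, can share reads and their values are uncertain. The table lists 23329 symbols, 21798 of them with a count. Of all symbols 21150 were in the reference annotation, 1977 only as an older name (Chi3l3 is now Chil3). Coordinates are from that reference, GRCm38.p6. Ly6g, part of the gate, is not analysed here.

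Each library's group and number came from its title. Before the data were examined, the groups, 11 comparisons, 20 gene lists, 14 marker lists, the alternatives and the rule for named genes were fixed. The lists cover microglia identity, microglia transcription factors, monocyte identity, monocyte-derived macrophage genes, MHC class I and class II presentation, interferon response, alternative activation, inflammatory cytokines, chemokine receptors and adhesion, matrix, hypoxia and glycolysis, disease-associated microglia, complement and phagocytosis, cholesterol synthesis, lipid efflux and storage, cell cycle, T cell suppression, growth factors and angiogenesis, and dissociation stress. The marker lists cover neurons, astrocytes, oligodendrocytes, their precursors or glioma cells, endothelial cells, pericytes or fibroblasts, T, NK and B cells, dendritic cells, neutrophils, red cells, platelets and border-associated macrophages, given as summed CPM. A sum is not specific to its cell type. In blood monocytes border-associated macrophage markers were at 2175 ± 98.0 CPM, astrocyte markers at 410 ± 136 and oligodendrocyte markers at 644 ± 88.6.

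Tests were run in R 4.3.3. Counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 15363 genes, scaled by TMM and fitted in edgeR 4.0.16 by the quasi-likelihood method with robust dispersion over all 20 libraries and 6 groups. Calls have a Benjamini-Hochberg adjusted p under 0.05, over all genes tested. Differences between models and between lineages in their response to the tumour were interaction contrasts of the same fit. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 20 lists of a comparison, and again with an estimated correlation. Of 144 list calls at the preset value, 33 held with the estimated one. Named genes are the 8 with the largest fold change per direction among called genes at 20 CPM or more in 1 group with no overlap between groups, up to 4 members of each list with the smallest p, the genes of the sort with Itga4, and for overlaps the 10 genes per direction with the largest smallest fold change. The text names some of these, and some genes that the rule picks are not reported here. Ddx3y, Rn45s, Chi3l3 and the genes of the closing tests on neutrophil and GL261-only genes fall outside the rule where they are given and were chosen after their values were seen.

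MG and BMDM with the same number in their titles were taken as 1 tumour. In deviations from the group means, same-numbered libraries correlated at r = 0.32, 0.22 and 0.20 in GEMM and 0.39, 0.22 and 0.39 in GL261, and the highest correlation with another number was −0.15, −0.01, −0.07, 0.04, 0.08 and −0.18, across genes. With every same-numbered correlation over 0.1, the numbers were taken to pair the libraries, and a fit with the number as a block over the 12 tumour libraries was an alternative. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 3.08, between blood monocyte libraries.

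The analysis was tested on simulated counts of 15363 genes with 200 changed. For GEMM BMDM against MG, edgeR recovered 40% of genes changed 2-fold and 85% of those changed 4-fold, with 12 false of 137 calls. DESeq2 recovered 58% and 88% with 42 false of 188 calls, and limma-voom 34% and 84% with 16 false of 134. For GEMM BMDM against monocytes edgeR recovered 52% and 89% with 4 false of 145 calls, and for the interaction of the models 15% and 65% with 8 false of 88. Small differences in a group of 3 can thus go uncalled. Counting error is smallest where depth is highest, and monocyte libraries (5077787 to 7801073 counts) are the shallowest.

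Alternatives were DESeq2 1.42.0, limma-voom with quality weights, DESeq2-type size factors in edgeR, no filter, a filter of CPM over 5 in 3 libraries, a fit without robust dispersion, a fit of only the groups compared, the replicate block, and leaving out each library. After seeing the data, the libraries of GL261 tumour 80769, monocytes 64820 and 64821, and monocytes 64817, 64818 and 64819 were also left out in turn. Unmatched columns numbered 0.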

Results

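RNA was sequenced from myeloid cells of mouse gliomas, normal brain and blood, giving 20 libraries in 6 groups. The tumours were of 2 kinds. The genetically engineered mouse model (GEMM) arose from PDGFB delivered by the RCAS avian retroviral vector together with a short hairpin against p53, and the other was the mouse glioma line GL261. Each of 3 tumours per model gave microglia (MG, the brain's resident macrophages) and bone-marrow-derived macrophages (BMDM, cells that came in from blood). The sort in the labels parts them by a Flt3-Cre lineage reporter, which turns descendants of bone marrow progenitors from red to green fluorescence. That reporter is described for the GEMM, and whether GL261 tumours carried it is not given in the sources used here. Microglia of normal brain (n = 3) and blood monocytes with high Ly6C (n = 5) stood for the states before the tumour. Each library's title carries a number, taken here as the animal's, that only the MG and BMDM of 1 tumour share. If those numbers are not animals, p-values measure only the spread between these samples. Total counts per library were 23064781 to 36297826 in GEMM MG, 30048409 to 32913488 in GEMM BMDM, 18113450 to 20934656 in GL261 MG and 18850626 to 22088979 in GL261 BMDM. They were 26421803 to 30391652 in normal MG and 5077787 to 7801073 in monocytes, so low genes were measured least precisely in monocytes. Levels are CPM (counts scaled to library size), mean ± SD, and log2 fold changes carry their SE, with n = 3 libraries per group and 5 for monocytes.

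Itga4, P2ry12 and Sall1, lineage genes that the described sort did not use, differed between MG and BMDM of each model in the direction of the labels. Itga4, which encodes the integrin chain CD49D (chromosome 2, 79255426 to 79333114 in GRCm38.p6, the assembly behind the mm10 build), was at 868 ± 323 CPM in monocytes, 105 ± 11.6 in GEMM BMDM, and 80.8 ± 8.01 in GL261 BMDM. In MG it was at 5.76 ± 2.75 CPM (GEMM), 20.5 ± 8.501 (GL261) and 1.25 ± 0.879 (normal). P2ry12, a purinergic receptor of microglia (chromosome 3, 59216271 to 59262985), ran the other way, from 6180 ± 528 CPM in normal MG through 1736 ± 614 in GEMM MG to 452 ± 273 in GL261 MG. It was at 266 ± 86.3 CPM in GEMM BMDM, 59.8 ± 12.3 in GL261 BMDM and 117 ± 35.5 in monocytes. Sall1, a transcription factor of microglia (chromosome 8, 89027242 to 89044162), was at 364 ± 15.1 CPM in normal MG, 191 ± 63.9 in GEMM MG, 86.8 ± 54.2 in GL261 MG, 13.9 ± 14.4 in GEMM BMDM and 0.866 ± 0.321 in GL261 BMDM. Ly6c2, a gene of the antigen that the tumour gate excluded, was at 1063 ± 193 CPM in monocytes, 48.7 ± 25.7 in GL261 BMDM and 5.42 ± 1.897 in GEMM BMDM, and its reads may be shared with near-identical Ly6 genes. Xist was at 144.7 to 617 CPM in the monocyte libraries and at most 2.73 CPM in any other group, while the Y-linked gene Ddx3y reached at most 2.82 CPM in monocytes and was at 46.3 CPM or more elsewhere, so each comparison with monocytes also compared sexes. Rn45s, the ribosomal precursor, took 13.5% and 14.3% of the counts of monocyte libraries 64820 and 64821 and 1.05% to 1.62% of the other 3.

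**Figure D1:**
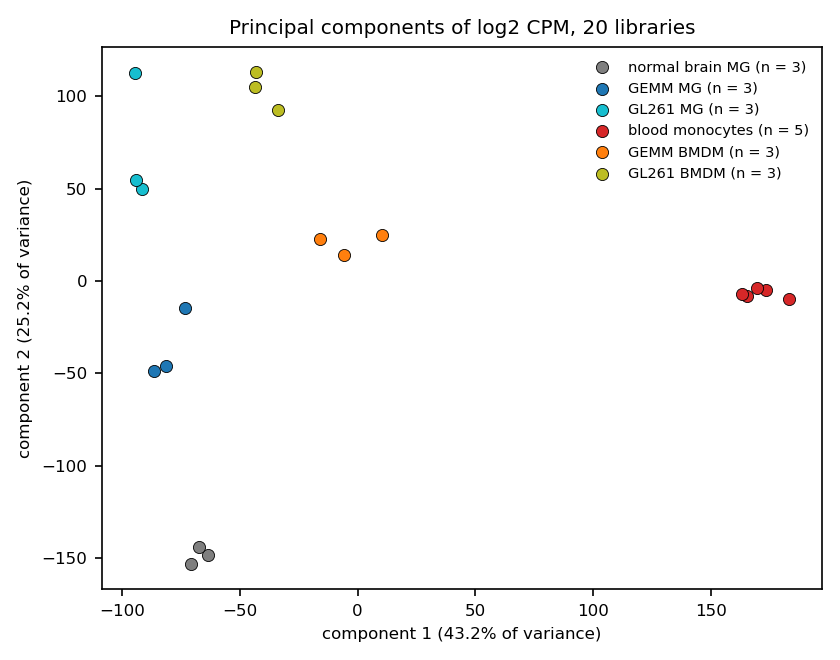
Principal components of the 20 libraries, computed on log2 CPM. Each point is 1 library, coloured by group, and the axes give component 1 (43.2% of the variance) against component 2 (25.2%).

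**Figure D2:**
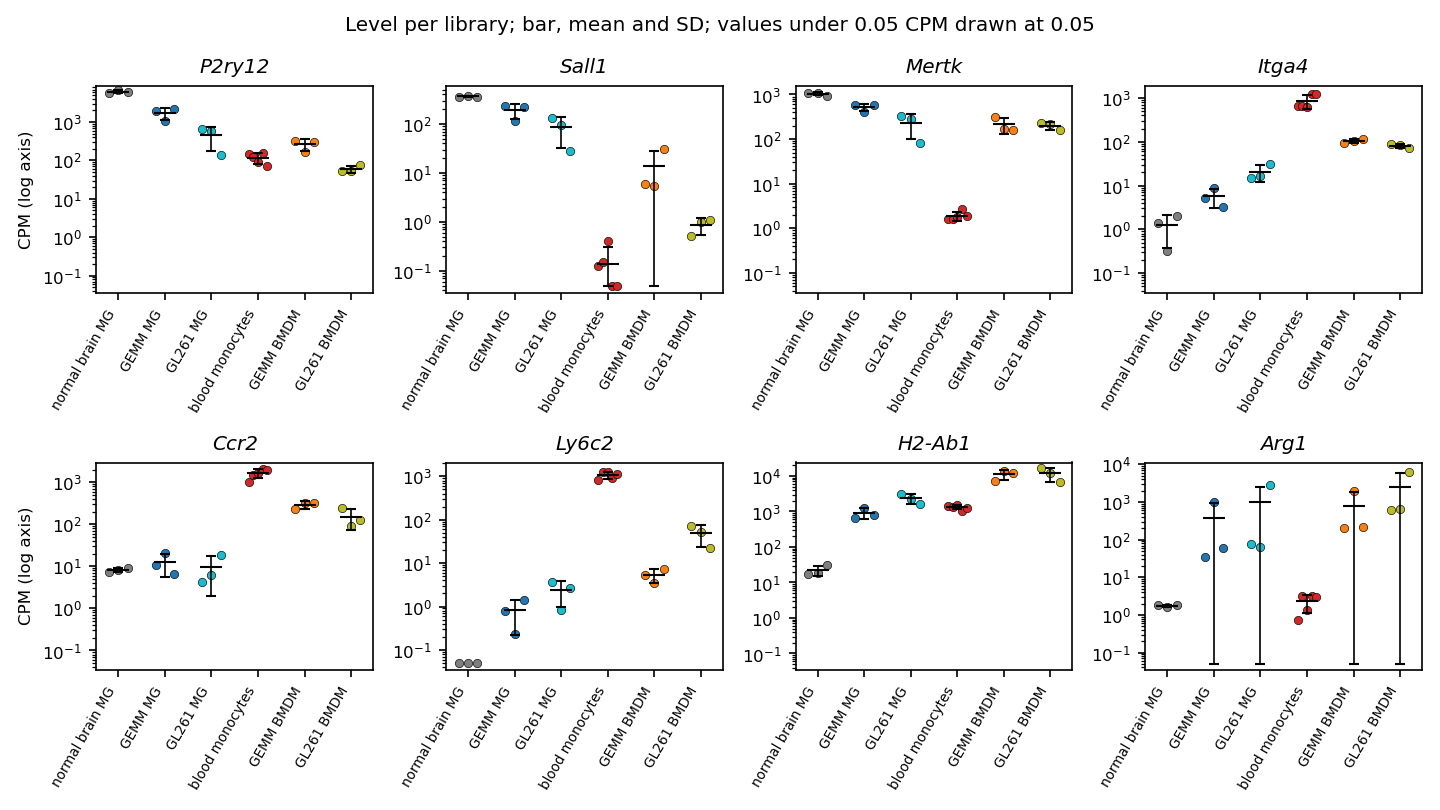
Level of 8 genes in each library (CPM, log axis), with the mean and SD of each group as bars and 1 point per library. Values under 0.05 CPM are drawn at 0.05. P2ry12 and Sall1 were highest in normal MG, and Itga4, Ccr2 and Ly6c2 in blood monocytes.

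The first question was which genes differ between macrophages of bone marrow origin and microglia of GEMM tumours. The main fit compared group means and did not use the pairing by tumour. The fit with the replicate block used it and lost 292 of the 3135 calls it tested. Several genes of MHC class II presentation, chemokine signalling and adhesion were higher in BMDM. Ccr2, the receptor that draws monocytes into tissue, was 23.2-fold higher (log2 4.54 ± 0.54, adjusted p = 1.32e-05; 292 ± 56.2 against 12.6 ± 7.02 CPM), and Itga4 18.0-fold higher (log2 4.17 ± 0.48, adjusted p = 1.08e-05). Ccr7, the receptor by which dendritic cells reach lymph nodes, was 35.5-fold higher (log2 5.15 ± 1.27), and the chemokines Ccl22 and Ccl17 32.97-fold and 25.9-fold higher. H2-Ab1, an MHC class II chain, was 12.2-fold higher (log2 3.61 ± 0.37), and Ciita, the master regulator of that pathway, 21.1-fold. Sall1 was 13.7-fold lower (log2 -3.77 ± 0.61, adjusted p = 0.000254), as were the fructose transporter Slc2a5 (14.2-fold), Crybb1 (11.6-fold) and the growth factor Csf1 (7.59-fold, log2 -2.92 ± 0.65).

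By list, microglia identity genes gave 24 lower and 2 not called of 26 (24 lower adjusted over the list alone, camera adjusted p = 6.33e-19, and adjusted p = 0.0635 with an estimated correlation). Monocyte identity genes gave 17 higher, 1 lower and 5 not called of 23 (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.43e-13, and adjusted p = 0.0108 with an estimated correlation). Plac8 (log2 4.46 ± 0.32) and Napsa (log2 4.92 ± 0.63) were among the higher monocyte genes. The list of monocyte-derived macrophage genes gave 14 higher and 6 not called of 20 (15 higher adjusted over the list alone, camera adjusted p = 1.83e-15, and adjusted p = 0.0108 with an estimated correlation). It holds Itga4 and other genes that may have been chosen on such libraries, so it is not taken as independent evidence. MHC class II presentation gave 13 higher and 3 not called of 16 (13 higher adjusted over the list alone, camera adjusted p = 6.61e-14, and adjusted p = 0.0428 with an estimated correlation). Chemokine receptors and adhesion gave 9 higher, 1 lower and 8 not called of 18 (10 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00034, and adjusted p = 0.0108 with an estimated correlation), with Itgb7 29.9-fold and Ccr1 14.8-fold higher. Hypoxia and glycolysis gave 2 higher, 9 lower and 13 not called of 24 (3 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.00171, and adjusted p = 0.451 with an estimated correlation). Pdk1, a kinase that inhibits pyruvate dehydrogenase, was 2.62-fold lower and Pfkp 8.47-fold higher. Cholesterol synthesis gave 6 higher, 1 lower and 11 not called of 18 (12 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.000603, and adjusted p = 0.277 with an estimated correlation), with the regulator Srebf2 3.72-fold higher. Complement and phagocytosis gave 2 higher, 10 lower and 11 not called of 23 (2 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.00034, and adjusted p = 0.126 with an estimated correlation), among them C1qc 2.16-fold lower. The interferon response gave 6 higher and 24 not called of 30 (6 higher adjusted over the list alone, camera adjusted p = 0.0561), and adjusted p = 0.0149 with the replicate block but adjusted p = 0.790 with an estimated correlation. Matrix genes had a median of -0.06 and a positive mean and test, with 5 higher, 5 lower and 17 not called of 27 (8 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.58). Summed dendritic cell markers were at 1206 ± 511 CPM in GEMM BMDM and 53.8 ± 35.7 in GEMM MG, beside the higher MHC class II genes. That sum holds Ccr7 and Ccl22, so it is not separate from them. T cell markers were at 60.6 ± 23.2 and 7.93 ± 4.57 CPM. Border-associated macrophage markers, which share F13a1 with monocyte identity, were at 1054 ± 443 and 154 ± 50.8 CPM. Platelet markers were at 100.1 ± 25.8 and 13.1 ± 5.28 CPM, and NK cell markers at 38.0 ± 18.0 and 5.73 ± 2.12. Neutrophil markers were at 895 ± 1156 CPM, with 2229 in GEMM BMDM 68702, and 389 ± 49.3.

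In all, 1949 genes were higher and 1245 lower in GEMM BMDM of 15363 tested. The lower count was 1900 with DESeq2 and 2038 with limma-voom. The higher count was 1125 without GEMM MG 68702, 1105 without GEMM MG BB30105 and 1279 without GEMM BMDM BB30101, which also left 722 lower.

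The same question was asked in GL261 tumours. Kmo, an enzyme of tryptophan breakdown, was 43.4-fold higher in BMDM (log2 5.44 ± 0.74, adjusted p = 7.95e-05), the decoy receptor Il1r2 37.3-fold (log2 5.22 ± 0.97) and the anti-inflammatory cytokine Il10 17.2-fold (log2 4.10 ± 0.63). Ccr2 was 15.8-fold higher (log2 3.98 ± 0.53, adjusted p = 5.4e-05; 152 ± 77.8 against 9.58 ± 7.59 CPM), Itga4 3.94-fold (log2 1.98 ± 0.44), and the lipid-sensing nuclear receptors Pparg and Nr1h3 10.4-fold and 8.22-fold. Lower genes included Siglech (log2 -6.91 ± 0.73, adjusted p = 7.42e-06; 2.51 ± 0.735 against 302 ± 209.8 CPM), Sall1 (log2 -6.63 ± 0.74), Slc2a5 (log2 -6.92 ± 0.93) and the B cell chemokine Cxcl13 (log2 -7.24 ± 1.63; 0.284 ± 0.312 against 43.4 ± 55.2 CPM). Crybb1 was 103-fold lower.

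Microglia identity genes gave 19 lower and 7 not called of 26 (22 lower adjusted over the list alone, camera adjusted p = 3.49e-19, and adjusted p = 0.095 with an estimated correlation). The transcription factors of microglia gave 2 higher, 6 lower and 4 not called of 12 (2 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0379, and adjusted p = 0.465 with an estimated correlation). Monocyte identity gave 14 higher, 1 lower and 8 not called of 23 (16 higher and 2 lower adjusted over the list alone, camera adjusted p = 6.01e-10, and adjusted p = 0.0388 with an estimated correlation), and the monocyte-derived macrophage list, which is not independent evidence, 13 higher and 7 not called of 20 (15 higher adjusted over the list alone, camera adjusted p = 1.45e-12, and adjusted p = 0.0428 with an estimated correlation). MHC class II presentation gave 11 higher and 5 not called of 16 (11 higher adjusted over the list alone, camera adjusted p = 3.6e-07, and adjusted p = 0.127 with an estimated correlation), with H2-Ab1 5.08-fold higher. Beside it, dendritic cell markers summed to 271 ± 261 CPM in GL261 BMDM and 38.8 ± 24.8 in GL261 MG. Alternative activation gave 8 higher and 10 not called of 18 (9 higher adjusted over the list alone, camera adjusted p = 3.62e-06, and adjusted p = 0.127 with an estimated correlation), with the scavenger receptor Msr1 5.49-fold and Il10 higher. Inflammatory cytokines gave 9 higher, 3 lower and 10 not called of 22 (9 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0379, and adjusted p = 0.465 with an estimated correlation), with Il1rn 5.54-fold and Ptgs2 4.66-fold higher. Lipid efflux and storage gave 9 higher, 2 lower and 7 not called of 18 (10 higher and 3 lower adjusted over the list alone, camera adjusted p = 9.54e-05, and adjusted p = 0.167 with an estimated correlation), with Apoc2 5.71-fold and Soat1 2.57-fold higher. T cell suppression gave 2 higher and 11 not called of 13 (3 higher adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.109 with an estimated correlation). Disease-associated microglia genes gave 7 higher, 3 lower and 14 not called of 24 (8 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.0782), and adjusted p = 0.00199 with the replicate block but adjusted p = 0.382 with an estimated correlation. Cst7 was 14.7-fold lower and Lyz2 5.83-fold higher. In complement and phagocytosis the median was 0.16 and the mean negative, with 5 higher, 6 lower and 12 not called of 23 (7 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.52). Border-associated macrophage markers summed to 4657 CPM in GL261 BMDM 80769 and 965 CPM in GL261 MG 80769, against group means of 2363 ± 1987 and 396 ± 493 CPM. Blood monocytes were at 2175 ± 98.0 CPM on the same list, so it does not single out border-associated macrophages. Red cell markers reached 1839 CPM in GL261 MG 80767.

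Of 15363 genes, 1646 were higher and 1046 lower in GL261 BMDM, 61.1% of the calls being higher against 50.6% with DESeq2. The lower count was 1768 with DESeq2 and 1857 with limma-voom, 669 without GL261 MG 80767 and 466 without GL261 BMDM 80766. With only the groups compared in the fit, 599 were higher and 234 lower, and 808 of 2553 calls were kept. The main fit shares its spread with the other groups, so its p-values for GL261 may be too small.

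Both models together show which differences between the lineages held in each. Napsa, Kmo and Ocstamp were among the genes higher in BMDM of both, by log2 4.92 ± 0.63 and 5.24 for Napsa, and Slc2a5, Sall1 and Cst7 among the lower. In the same direction, 912 genes were higher and 510 lower in both, against 208.8 and 84.8 for independent lists, and 15 moved in opposite directions. Fold changes correlated across genes at r = 0.56, although genes are not independent replicates. The shared lower count was 827 with DESeq2, 894 with limma-voom and 324 without GL261 BMDM 80766. With only the groups compared, 400 and 174 were shared.

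The difference between the models was tested directly as an interaction. Sgk1, a kinase induced by stress hormones, differed by log2 2.38 ± 0.31, adjusted p = 0.0013, being at 1167 ± 200.5 CPM in GL261 BMDM and 391 ± 98.3 in GL261 MG but 737 ± 60.1 and 1283 ± 251 in GEMM. Kit, the stem cell factor receptor, differed by log2 -5.01 ± 0.92, adjusted p = 0.0109, at 119 ± 39.1 against 4.71 ± 3.66 CPM in GEMM BMDM and MG and 44.1 ± 4.06 against 57.6 ± 27.8 in GL261. Ly75, an endocytic receptor of dendritic cells, differed by log2 -5.01 ± 0.78, the kinase Lrrk2 by log2 -4.52 ± 0.41 and the inhibitory Fc receptor Fcgr2b by log2 1.75 ± 0.26. Disease-associated microglia genes gave 3 higher and 21 not called of 24 (4 higher adjusted over the list alone, camera adjusted p = 1.39e-07, and adjusted p = 0.0323 with an estimated correlation). Complement and phagocytosis gave 4 higher and 19 not called of 23 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 3.61e-07, and adjusted p = 0.0531 with an estimated correlation). Hypoxia and glycolysis gave 2 higher and 22 not called of 24 (7 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.84e-05, and adjusted p = 0.359 with an estimated correlation). Higher means a larger BMDM to MG ratio in GL261. Inflammatory cytokines gave 22 not called of 22 (0 adjusted over the list alone, camera adjusted p = 0.000683, and adjusted p = 0.359 with an estimated correlation). MHC class II presentation gave 1 lower and 15 not called of 16 (1 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.000199, and adjusted p = 0.359 with an estimated correlation). With the replicate block, monocyte identity (adjusted p = 0.0723 without it) reached adjusted p = 0.0365, the monocyte-derived macrophage list (0.0723) 0.046 and cell cycle (0.173) 0.0333. With an estimated correlation these 3 had adjusted p = 0.681, 0.777 and 0.825. Median and mean or test differed in sign for microglia identity, microglia transcription factors, chemokine receptors, growth factors and dissociation stress, none of them called.

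In this interaction 93 genes were higher and 157 lower, and the counts moved with most settings. They were 366 and 428 with DESeq2, 384 and 435 with limma-voom, 43 higher with no filter and 7 and 14 with only the groups compared. With the replicate block they were 105 and 192, and 144 of the 250 calls were kept. Leaving out 1 library gave 54 and 49 (GEMM MG 68702), 170 higher (GEMM MG BB30101), 71 lower (GEMM MG BB30105), 280 higher (GEMM BMDM 68702), 33 and 69 (GEMM BMDM BB30101), and 50 and 104 (GEMM BMDM BB30105). Among GL261 libraries it gave 141 higher (GL261 MG 80766), 48 higher (GL261 MG 80767), 61 lower (GL261 BMDM 80766), 202 higher (GL261 BMDM 80767), and 61 higher (GL261 BMDM 80769). For normal MG, which share the estimate of the spread, it gave 104 lower (normal MG 67572), 140 higher (normal MG 67573) and 104 lower (normal MG 67574). No batch label separates the models, so model and batch cannot be told apart.

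The next question was how cells sorted as MG from tumours differ from normal MG. In GEMM tumours, Spp1, the matrix protein osteopontin, was 99.7-fold higher than in normal MG (log2 6.64 ± 0.78, adjusted p = 3.33e-06), the scavenger receptor Cd36 89.3-fold and the lectin Lgals3 108-fold. H2-Eb1 was 69.8-fold higher (log2 6.13 ± 0.47), the interferon-induced sensor Zbp1 79.8-fold and the proliferation gene Mki67 21.4-fold (log2 4.42 ± 0.35). Vegfa, the main angiogenic factor, was 7.07-fold higher (log2 2.82 ± 0.53) and Cd274, which encodes PD-L1, 4.398-fold. P2ry12 was 3.56-fold lower (log2 -1.83 ± 0.44, adjusted p = 0.00263), the kinesin Kif5a 18.6-fold and Jun 8.97-fold.

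Disease-associated microglia genes gave 23 higher and 1 not called of 24 (23 higher adjusted over the list alone, camera adjusted p = 7.89e-21, and adjusted p = 0.000314 with an estimated correlation), with Axl 37.4-fold and Cst7 85.1-fold higher. Interferon response gave 27 higher and 3 not called of 30 (27 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.11e-26, and adjusted p = 0.0399 with an estimated correlation). Cell cycle gave 24 higher of 24 (24 higher adjusted over the list alone, camera adjusted p = 2.15e-19, and adjusted p = 0.0452 with an estimated correlation). Hypoxia and glycolysis gave 20 higher and 4 not called of 24 (20 higher adjusted over the list alone, camera adjusted p = 3.9e-14, and adjusted p = 0.0399 with an estimated correlation). MHC class I presentation gave 13 higher and 2 not called of 15 (13 higher adjusted over the list alone, camera adjusted p = 6.79e-10, and adjusted p = 0.0542 with an estimated correlation). MHC class II presentation gave 11 higher, 1 lower and 4 not called of 16 (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.57e-08, and adjusted p = 0.0542 with an estimated correlation). Lipid efflux and storage gave 14 higher and 4 not called of 18 (16 higher adjusted over the list alone, camera adjusted p = 9.01e-13, and adjusted p = 0.0258 with an estimated correlation). Matrix and matrix remodelling gave 21 higher and 6 not called of 27 (21 higher adjusted over the list alone, camera adjusted p = 9.38e-08, and adjusted p = 0.012 with an estimated correlation). Growth factors and angiogenesis gave 10 higher, 1 lower and 9 not called of 20 (10 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0157, and adjusted p = 0.0404 with an estimated correlation). Microglia identity gave 1 higher, 13 lower and 12 not called of 26 (1 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.00503, and adjusted p = 0.413 with an estimated correlation). Dissociation stress, which tracks handling of the tissue, gave 1 higher, 13 lower and 6 not called of 20 (1 higher and 14 lower adjusted over the list alone, camera adjusted p = 0.000234, and adjusted p = 0.168 with an estimated correlation). Lists of the other lineage were also higher in cells sorted as MG. Monocyte identity gave 15 higher, 1 lower and 7 not called of 23 (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.23e-07, and adjusted p = 0.0404 with an estimated correlation). The monocyte-derived macrophage list, which is not independent evidence, gave 17 higher and 3 not called of 20 (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.67e-08, and adjusted p = 0.0542 with an estimated correlation). Neuron markers summed to 28.0 ± 7.60 CPM in normal MG and 8.26 ± 1.10 in GEMM MG, beside the lower Kif5a, and astrocyte markers to 544 ± 86.8 and 162.5 ± 35.2 CPM. Astrocyte markers were also at 410 ± 136 CPM in blood monocytes, so their sum is not specific to astrocytes. Markers of oligodendrocyte precursors or glioma cells summed to 217 ± 44.9 CPM in GEMM MG and 10.4 ± 4.86 in normal MG, beside the higher cell cycle genes. In all, 3527 genes were higher and 3204 lower in GEMM MG.

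In GL261 tumours the same comparison gave 1826-fold higher Gpnmb, a glycoprotein of lipid-laden macrophages (log2 10.83 ± 0.80, adjusted p = 1.18e-08), 286-fold higher complement factor Cfb (log2 8.16 ± 0.57) and 185-fold higher fibronectin Fn1. H2-Eb1 was 168-fold higher (log2 7.39 ± 0.49), Ifitm3 58.6-fold, Mki67 26.6-fold and the cholesterol synthesis enzyme Sqle 11.5-fold (log2 3.53 ± 0.39). P2ry12 was 13.7-fold lower (log2 -3.77 ± 0.48, adjusted p = 3.39e-06), Gpr34 14.4-fold, and the transcription factor Mef2c 4.95-fold.

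Microglia identity gave 24 lower and 2 not called of 26 (24 lower adjusted over the list alone, camera adjusted p = 1.99e-08, and adjusted p = 0.167 with an estimated correlation). Microglia transcription factors gave 9 lower and 3 not called of 12 (9 lower adjusted over the list alone, camera adjusted p = 0.00097, and adjusted p = 0.175 with an estimated correlation). Interferon response gave 28 higher and 2 not called of 30 (28 higher adjusted over the list alone, camera adjusted p = 5.24e-23, and adjusted p = 0.128 with an estimated correlation). MHC class I presentation gave 15 higher of 15 (15 higher adjusted over the list alone, camera adjusted p = 1.1e-10, and adjusted p = 0.128 with an estimated correlation). Cell cycle gave 23 higher and 1 not called of 24 (23 higher adjusted over the list alone, camera adjusted p = 7.24e-15, and adjusted p = 0.129 with an estimated correlation). Cholesterol synthesis gave 12 higher and 6 not called of 18 (12 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00289, and adjusted p = 0.25 with an estimated correlation). Alternative activation gave 11 higher, 3 lower and 4 not called of 18 (11 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.232). Inflammatory cytokines gave 10 higher, 4 lower and 8 not called of 22 (10 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.232). T cell suppression gave 7 higher, 5 lower and 1 not called of 13 (7 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.872). Dissociation stress gave 1 higher, 16 lower and 3 not called of 20 (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 5.73e-06, and adjusted p = 0.129 with an estimated correlation). Here too, monocyte identity gave 19 higher, 1 lower and 3 not called of 23 (19 higher and 1 lower adjusted over the list alone, camera adjusted p = 1.55e-05, and adjusted p = 0.129 with an estimated correlation). For the monocyte-derived macrophage list, not independent evidence, the result was 17 higher, 1 lower and 2 not called of 20 (17 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.27e-06, and adjusted p = 0.129 with an estimated correlation). Markers of oligodendrocyte precursors or glioma cells summed to 719 ± 267 CPM in GL261 MG, 331 ± 109 in GL261 BMDM, 217 ± 44.9 in GEMM MG, 74.95 ± 52.2 in GEMM BMDM and 10.4 ± 4.86 in normal MG. Border-associated macrophage markers were at 396 ± 493 CPM in GL261 MG (965 in 80769, 138 in 80766 and 85.6 in 80767) and 55.4 ± 14.9 in normal MG. Chi3l3, in the monocyte identity and alternative activation lists, was at 4421 CPM in 80769, 0.0429 in 80766 and 1.24 in 80767. T cell markers were at 16.8 ± 5.95 and 1.19 ± 0.287 CPM in GL261 and normal MG, and NK cell markers at 13.7 ± 3.53 and 0.760 ± 0.224. Counts were 4701 higher and 4178 lower.

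Arg1, an enzyme of alternatively activated macrophages (chromosome 10, 24915207 to 24927470), was among the genes higher in MG of both models, at 376 ± 569 and 976 ± 1571 CPM against 1.76 ± 0.132 in normal MG. It was uneven between tumours, at 1032 CPM in GEMM MG BB30101, 34.1 and 60.7 in the other GEMM MG, 2790 in GL261 MG 80769 and 74.8 and 62.3 in the other GL261 MG. Both models shared 2664 higher and 2381 lower genes, against 1079 and 871.3 for independent lists, and 142 moved in opposite directions. In 10 simulations of unchanged groups with the same controls 0 genes were shared, which holds for no effect at all and does not measure what the controls add to real effects. Fold changes correlated at r = 0.66 across genes (simulated 0.48), with a covariance of 2.42 against 0.188 simulated, a difference of 2.23. Part of the excess may come from the 3 shared normal libraries, which were not split, since 1 part would hold 1 library. Sox10, a marker of oligodendrocyte precursors or glioma cells, was among the shared higher genes (log2 7.56 or more in both models). RNA of such cells may also add to the overlap, which was not tested.

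For the cells of bone marrow origin, the state before the tumour was the blood monocyte. In GEMM BMDM the complement chain C1qa was 425-fold higher than in monocytes (log2 8.73 ± 0.29, adjusted p = 2.39e-13), the matrix protease Mmp14 454-fold, Spp1 408-fold and the receptor for dying cells Mertk 115-fold (log2 6.85 ± 0.39). Apoe, the lipid carrier (chromosome 7, 19696244 to 19701310), was 19.7-fold higher (log2 4.30 ± 0.40; 43850 ± 26520 against 2229 ± 411 CPM), and Vegfa 39.95-fold. Ly6c2 was 196-fold lower (log2 -7.62 ± 0.63) and Itga4 8.302-fold (log2 -3.05 ± 0.43, adjusted p = 1.14e-05). Monocytes were taken for high Ly6C and tumour cells as Ly6C-negative, so the sort itself favours a lower Ly6c2. Ly6c2 is also in the monocyte identity list.

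Complement and phagocytosis gave 16 higher, 2 lower and 5 not called of 23 (16 higher and 2 lower adjusted over the list alone, camera adjusted p = 1.13e-14, and adjusted p = 0.0104 with an estimated correlation). Alternative activation gave 14 higher and 4 not called of 18 (14 higher adjusted over the list alone, camera adjusted p = 5.57e-06, and adjusted p = 0.134 with an estimated correlation). Inflammatory cytokines gave 20 higher and 2 not called of 22 (20 higher adjusted over the list alone, camera adjusted p = 2.07e-11, and adjusted p = 0.0234 with an estimated correlation), with Cxcl2 74.9-fold higher. Microglia identity genes gave 21 higher, 1 lower and 4 not called of 26 (21 higher and 1 lower adjusted over the list alone, camera adjusted p = 8.27e-09, and adjusted p = 0.152 with an estimated correlation), with Olfml3 183-fold and Trem2 13.1-fold higher. Monocyte identity gave 1 higher, 20 lower and 2 not called of 23 (1 higher and 20 lower adjusted over the list alone, camera adjusted p = 1.54e-08, and adjusted p = 0.0462 with an estimated correlation). Growth factors and angiogenesis gave 14 higher, 1 lower and 5 not called of 20 (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000109, and adjusted p = 0.0112 with an estimated correlation). T cell suppression gave 9 higher and 4 not called of 13 (9 higher adjusted over the list alone, camera adjusted p = 0.00828, and adjusted p = 0.0775 with an estimated correlation). Cholesterol synthesis gave 1 higher, 12 lower and 5 not called of 18 (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.00143, and adjusted p = 0.236 with an estimated correlation). For the interferon response the median was 0.11 with a positive mean and a negative test, and 7 higher, 6 lower and 17 not called of 30 (7 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.883). Dissociation stress gave 15 higher, 1 lower and 4 not called of 20 (15 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.37e-06, and adjusted p = 0.135 with an estimated correlation). Neutrophil markers summed to 12174 ± 10685 CPM in monocytes and 895 ± 1156 in GEMM BMDM (2229 in library 68702), and platelet markers to 1621 ± 501 and 100.1 ± 25.8 CPM. Dendritic cell markers, which share Ccl22 with alternative activation, were at 216 ± 41.3 CPM in monocytes and 1206 ± 511 in GEMM BMDM. Markers of oligodendrocyte precursors or glioma cells were at 2.88 ± 2.13 and 74.95 ± 52.2 CPM. Counts were 4859 higher and 3941 lower. DESeq2-type size factors shift the median gene by −0.11 and gave 4351 higher and 4398 lower, so which direction held more calls depends on the scaling.

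In GL261 BMDM, Gpnmb was 640.0-fold higher than in monocytes (log2 9.32 ± 0.61, adjusted p = 1.14e-09), Mmp14 659-fold, C1qa 525-fold (log2 9.04 ± 0.29), the chemokine Ccl7 289-fold and Cxcl9 66.6-fold. The vitamin D receptor Vdr was 43.95-fold higher and Mertk 107-fold (log2 6.74 ± 0.39). Ly6c2, whose direction the Ly6C gates favour, was 21.8-fold lower (log2 -4.45 ± 0.54), Itgb7 16.3-fold, Plac8 18.8-fold and Itga4 10.7-fold (log2 -3.42 ± 0.44, adjusted p = 3.17e-06).

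Complement and phagocytosis gave 17 higher, 3 lower and 3 not called of 23 (17 higher and 3 lower adjusted over the list alone, camera adjusted p = 4.7e-16, and adjusted p = 0.0057 with an estimated correlation). Matrix and matrix remodelling gave 19 higher, 4 lower and 4 not called of 27 (19 higher and 4 lower adjusted over the list alone, camera adjusted p = 3.48e-05, and adjusted p = 0.0387 with an estimated correlation). Cell cycle gave 23 higher and 1 not called of 24 (23 higher adjusted over the list alone, camera adjusted p = 1.34e-11, and adjusted p = 0.152 with an estimated correlation), with Mcm3 7.43-fold higher. Monocyte identity gave 1 higher, 20 lower and 2 not called of 23 (1 higher and 20 lower adjusted over the list alone, camera adjusted p = 1.48e-08, and adjusted p = 0.0391 with an estimated correlation). Disease-associated microglia genes gave 15 higher, 3 lower and 6 not called of 24 (15 higher and 3 lower adjusted over the list alone, camera adjusted p = 9.25e-05, and adjusted p = 0.0391 with an estimated correlation). Microglia transcription factors had a median of -0.24 and a positive mean and test, with 4 higher, 6 lower and 2 not called of 12 (4 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.645). Lipid efflux and storage gave 8 higher, 1 lower and 9 not called of 18 (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.193). Endothelial markers summed to 212 ± 124 CPM in GL261 BMDM and 149 ± 13.5 in monocytes, NK cell markers to 38.7 ± 7.03 and 113 ± 86.0, and B cell markers to 11.5 ± 4.50 and 287 ± 229. Neutrophil markers were at 158 ± 39.0 CPM in GL261 BMDM against 12174 ± 10685 in monocytes, and platelet markers at 112 ± 38.8 against 1621 ± 501. Beside the higher cell cycle genes, markers of oligodendrocyte precursors or glioma cells were at 331 ± 109 CPM against 2.88 ± 2.13 in monocytes. Counts were 5237 higher and 4435 lower.

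C1qa, Spp1, Mmp14 and Ccl8 were among the genes higher than in monocytes in BMDM of both models, and Cd177 and Tubb1 among the lower. The neutrophil markers Camp and Ltf and the platelet markers Gp1bb and Gp5 were also among the lower. Both marker sums were far higher in monocytes than in BMDM, so lower genes here may belong to other blood cells. The Y-linked Uty was among the higher genes, where the sexes differ. The models shared 3847 higher and 3210 lower genes, against 1656 and 1138 for independent lists, and 109 moved in opposite directions. Simulated groups without effects again shared 0. Fold changes correlated at r = 0.75 across genes (simulated 0.53), with a covariance of 3.78 against 0.213 simulated, a difference of 3.56. With the monocytes split, 3 for GEMM and 2 for GL261, 3187 and 2589 were shared (1236 and 827 for independent lists, r = 0.69), and with 2 and 3 libraries 3084 and 2496 (1201 and 797.2, r = 0.68).

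Microglia of the 2 models were then compared with each other. Gpnmb was 11.3-fold higher in GL261 MG (SE of log2 0.57, adjusted p = 0.00019), Sqle 5.29-fold and the interferon-induced Gbp5 3.98-fold. Lower genes were the lipase Lpl (20.5-fold, log2 -4.36 ± 0.57, adjusted p = 3.2e-05), Fcrls (11.5-fold), the cholesterol exporter Abcg1 (6.85-fold) and Cx3cr1, the fractalkine receptor (5.36-fold, log2 -2.42 ± 0.60). Microglia identity gave 18 lower and 8 not called of 26 (18 lower adjusted over the list alone, camera adjusted p = 4.62e-08, and adjusted p = 0.394 with an estimated correlation). Lipid efflux and storage gave 12 lower and 6 not called of 18 (13 lower adjusted over the list alone, camera adjusted p = 8.61e-07, and adjusted p = 0.283 with an estimated correlation). Cholesterol synthesis gave 9 higher and 9 not called of 18 (11 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000942, and adjusted p = 0.394 with an estimated correlation). Disease-associated microglia genes gave 1 higher, 13 lower and 10 not called of 24 (1 higher and 16 lower adjusted over the list alone, camera adjusted p = 9.05e-07, and adjusted p = 0.0705 with an estimated correlation). Inflammatory cytokines gave 10 lower and 12 not called of 22 (12 lower adjusted over the list alone, camera adjusted p = 0.00216, and adjusted p = 0.394 with an estimated correlation). Interferon response gave 10 higher and 20 not called of 30 (9 higher adjusted over the list alone, camera adjusted p = 0.0113, and adjusted p = 0.662 with an estimated correlation). Alternative activation and growth factors had medians and means or tests of different sign and were not called (adjusted p = 0.343 and 0.279). Pericyte or fibroblast markers summed to 86.3 ± 56.7 CPM in GL261 MG and 23.6 ± 7.46 in GEMM MG, and oligodendrocyte markers to 428 ± 99.6 and 174 ± 12.998. Oligodendrocyte markers were at 644 ± 88.6 CPM in blood monocytes, so their sum is not specific to oligodendrocytes. Beside the lower microglia identity genes, markers of oligodendrocyte precursors or glioma cells were at 719 ± 267 CPM in GL261 MG, with 1019.7 in 80769, against 217 ± 44.9 in GEMM MG. Border-associated macrophage markers were at 396 ± 493 CPM, with 965 in 80769 and 85.6 and 138 in the other GL261 MG, against 154 ± 50.8. Red cell markers were at 623 ± 1054 and 9.84 ± 12.6 CPM. Counts were 2892 higher and 2383 lower, the higher count being 1811 without GEMM MG 68702 and 1924 without GEMM MG BB30105.

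Between the BMDM of the 2 models, the protease inhibitor Timp1 was 15.03-fold higher in GL261 (log2 3.91 ± 0.54, adjusted p = 9.7e-05), C3 7.13-fold (log2 2.83 ± 0.39), Ly6c2 8.99-fold and the checkpoint ligand Cd276 5.13-fold. Sall1 was 15.9-fold lower (log2 -3.99 ± 0.69, adjusted p = 0.000683), Siglech 37.3-fold, and the chemokines Ccl17 and Ccl22 12.5-fold and 6.997-fold. Microglia identity gave 17 lower and 9 not called of 26 (18 lower adjusted over the list alone, camera adjusted p = 1.26e-11, and adjusted p = 0.552 with an estimated correlation). Matrix and matrix remodelling gave 11 higher, 3 lower and 13 not called of 27 (13 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0146, and adjusted p = 0.552 with an estimated correlation). Cell cycle gave 5 higher and 19 not called of 24 (6 higher adjusted over the list alone, camera adjusted p = 0.00147, and adjusted p = 0.567 with an estimated correlation). Lipid efflux and storage gave 1 higher, 10 lower and 7 not called of 18 (2 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.000414, and adjusted p = 0.552 with an estimated correlation). Cholesterol synthesis gave 7 higher and 11 not called of 18 (10 higher adjusted over the list alone, camera adjusted p = 0.000565, and adjusted p = 0.566 with an estimated correlation). MHC class II presentation gave 2 lower and 14 not called of 16 (2 lower adjusted over the list alone, camera adjusted p = 0.0364, and adjusted p = 0.567 with an estimated correlation). Monocyte identity and alternative activation had a positive median and a negative test and were not called (adjusted p = 0.426 and 0.94). Dendritic cell markers, which include Ccl22, summed to 271 ± 261 CPM in GL261 BMDM, beside the lower Ccl17, and to 1206 ± 511 in GEMM BMDM. Beside the higher cell cycle genes, markers of oligodendrocyte precursors or glioma cells were at 331 ± 109 CPM in GL261 BMDM and 74.95 ± 52.2 in GEMM BMDM. Border-associated macrophage markers were at 2363 ± 1987 CPM, with 4657 in 80769, against 1054 ± 443. Neutrophil markers were at 158 ± 39.0 CPM against 895 ± 1156, with 2229 in GEMM BMDM 68702. Red cell markers were at 184 ± 272 and 6.39 ± 6.52 CPM, and T cell markers at 21.9 ± 5.56 and 60.6 ± 23.2. Counts were 1573 higher (1045 without GEMM BMDM BB30101) and 1454 lower (936 without GEMM BMDM 68702, 822 without GL261 BMDM 80767 and 707 with only the groups compared).

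Monocytes and normal MG were compared as the cells outside tumours. Plac8 was 1364-fold higher in monocytes (log2 10.41 ± 0.42, adjusted p = 1.9e-12), Itga4 684-fold (log2 9.42 ± 0.61), Cd44 668-fold and Ifitm3 157-fold. The transcription factor Runx3 was at 56.4 ± 2.85 CPM in monocytes and 0.139 ± 0.0616 in normal MG. Mertk was 547-fold lower (log2 -9.10 ± 0.42, adjusted p = 8.71e-12), C1qa 526-fold and Slc2a5 1325-fold. Microglia identity gave 26 lower of 26 (26 lower adjusted over the list alone, camera adjusted p = 3.4e-21, and adjusted p = 0.0693 with an estimated correlation). Monocyte identity gave 22 higher and 1 not called of 23 (22 higher adjusted over the list alone, camera adjusted p = 1e-17, and adjusted p = 0.00977 with an estimated correlation). Chemokine receptors and adhesion gave 12 higher, 4 lower and 2 not called of 18 (12 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.00073, and adjusted p = 0.0356 with an estimated correlation). Dissociation stress gave 1 higher, 18 lower and 1 not called of 20 (1 higher and 18 lower adjusted over the list alone, camera adjusted p = 4.16e-10, and adjusted p = 0.0818 with an estimated correlation). Markers of other blood cells moved with this comparison, neutrophil markers being at 12174 ± 10685 CPM in monocytes and 618 ± 20.3 in normal MG. Platelet markers were at 1621 ± 501 and 38.4 ± 4.10 CPM, and B cell markers at 287 ± 229 and 34.5 ± 7.69. Alternative activation, hypoxia and T cell suppression had medians and means or tests of different sign and were not called (adjusted p = 0.434, 0.884 and 0.361). Counts were 4673 higher and 4971 lower. DESeq2-type size factors shift the median gene by 0.10 (0.11 in DESeq2 itself) and gave 5059 higher and 4559 lower. Of these calls, 704 higher genes, with Napsa, Kmo and Il1r2 among them, and 435 lower genes, with Slc2a5, Sall1 and Csmd3, had the same direction in BMDM against MG of both models, where independent lists would share 63.5 and 27.4. These were 15.1% of the higher and 8.75% of the lower calls. In BMDM against MG, 234 of the calls had the opposite direction in GEMM and 349 in GL261. The lower count was 670 with DESeq2, 769 with limma-voom and 281 without GL261 BMDM 80766. With only the groups compared, 325 and 154 were kept.

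The change from monocyte to BMDM minus that from normal to tumour MG, averaged over the models, was tested as a difference in tumour response. No BMDM came from outside a tumour, so the change from monocyte to BMDM also holds differences of tissue, gate, sex and maturation. The contrast therefore cannot credit a difference to the tumour alone. Mertk and C1qa, for instance, were already far lower in monocytes than in normal MG. Mertk (log2 8.38 ± 0.47, adjusted p = 3.01e-10) and C1qa (log2 8.55 ± 0.32) had a positive difference, a more positive change in the bone marrow lineage. Vim (log2 -8.42 ± 0.75, adjusted p = 7.03e-08), Lgals3 (log2 -7.12 ± 0.59), Cd44 (log2 -7.86 ± 0.46), Itga4 (log2 -6.34 ± 0.59) and Mki67 (log2 -4.35 ± 0.39) had a negative one. Itga4 was lower in BMDM than in monocytes and higher in tumour MG than in normal MG, in both models. Microglia identity gave 22 higher and 4 not called of 26 (23 higher adjusted over the list alone, camera adjusted p = 1.69e-14, and adjusted p = 0.0742 with an estimated correlation). Interferon response gave 24 lower and 6 not called of 30 (26 lower adjusted over the list alone, camera adjusted p = 9.98e-20, and adjusted p = 0.0742 with an estimated correlation). Dissociation stress gave 18 higher, 1 lower and 1 not called of 20 (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.04e-12, and adjusted p = 0.0612 with an estimated correlation). Matrix genes had a negative median and mean and a positive test and were not called, and complement and phagocytosis had a median of -0.04 with 10 higher, 7 lower and 6 not called of 23 (11 higher and 7 lower adjusted over the list alone, camera adjusted p = 1.04e-05, and adjusted p = 0.0742 with an estimated correlation). Counts were 3972 higher and 3330 lower. DESeq2-type size factors shift the median gene by −0.16 and gave 3313 higher and 3887 lower. Of all genes, 1333 were higher and 898 lower in all 4 comparisons of tumour with normal cells (116.4 and 64.5 for independent lists). The comparisons share controls in pairs, so part of the excess may come from these, and the 0 genes in 10 simulations without effects do not measure it. Among them Gpnmb, the proton pump subunit Atp6v0d2 and the elastase Mmp12 were higher, Mmp12 at 154 ± 213 CPM in GEMM MG and 564 ± 656 in GL261 BMDM against 1.84 ± 0.564 in normal MG and 0.675 ± 0.482 in monocytes. Zbtb16, a transcription factor of innate lymphocytes, was lower, at 0.216 ± 0.222 and 0.355 ± 0.407 CPM against 6.79 ± 2.698 and 26.1 ± 11.6. Olig2, a marker of oligodendrocyte precursors or glioma cells, was also higher in all 4, by log2 6.33 or more. Those markers summed to 217 and 719 CPM in GEMM and GL261 MG and 74.95 and 331 in their BMDM. They were at 10.4 CPM in normal MG and 2.88 in monocytes. RNA of such cells in the tumour libraries may add to the overlap, which was not tested.

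**Figure D3:**
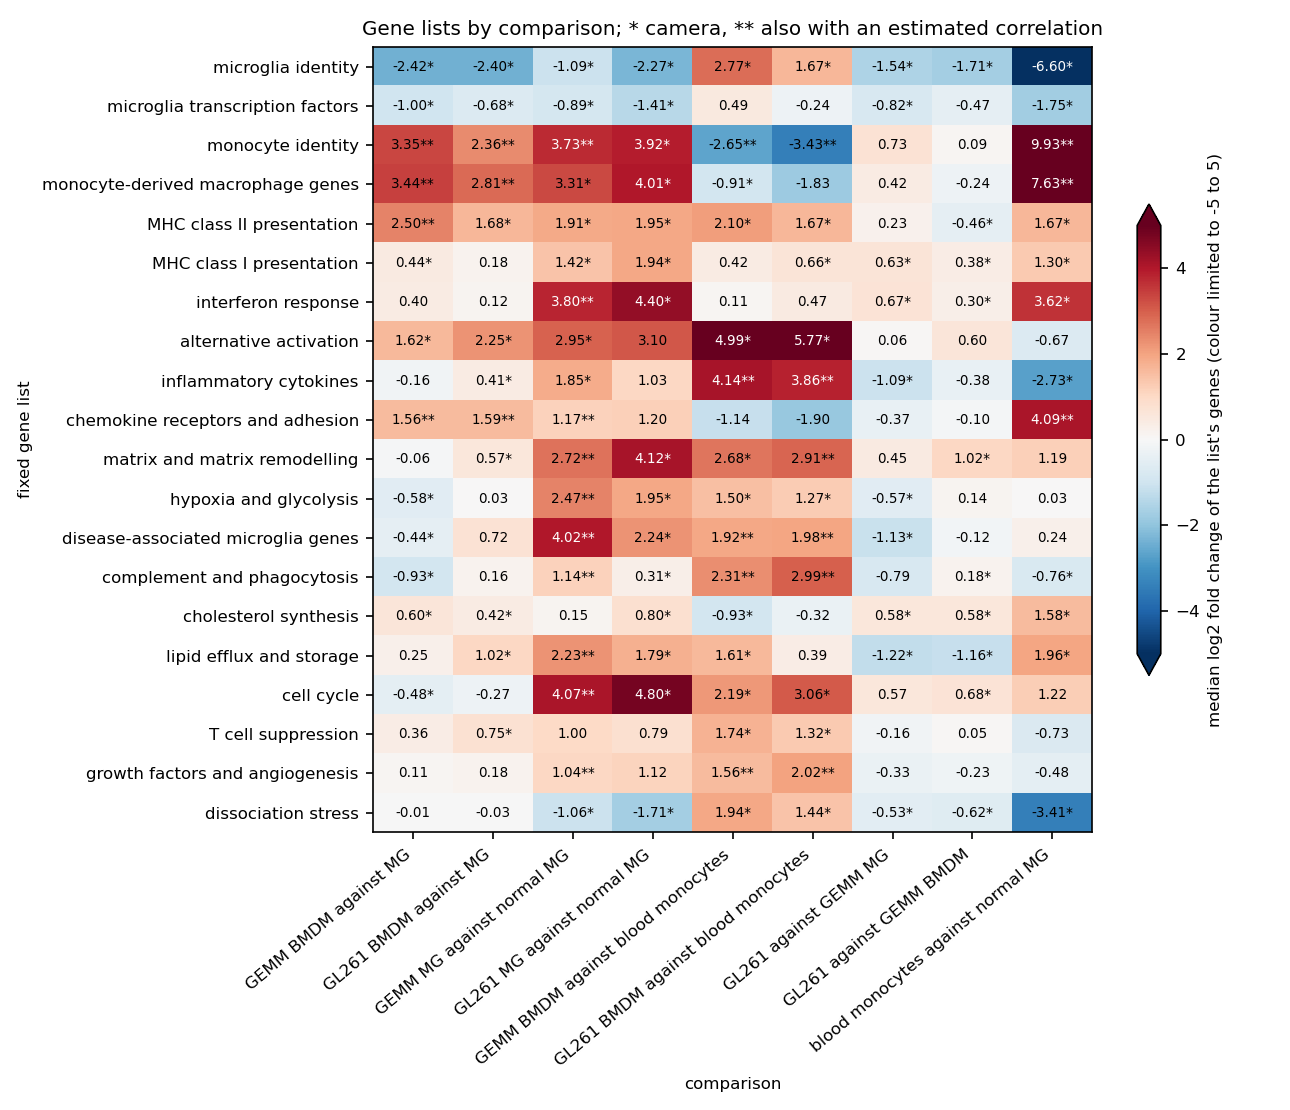
Median log2 fold change (colour) of the 20 gene lists in 9 comparisons. One star marks a camera adjusted p under 0.05 and a pair of stars a call that also held with an estimated correlation, such as the 23 of 24 disease-associated microglia genes higher in GEMM MG than in normal MG.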

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

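The test of genes seen only in GL261 libraries and the 11 tests on other splits of the samples were set before the results were seen, and the other tests in this part after.

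Monocyte library 64817 stood apart from the other 4 in summed T cell markers (114.5 CPM) and NK cell markers (260.9 CPM). These were among 23 measures tested in the only group of more than 3 libraries. Chance marks about 1 in 20 such measures, so flags among 23 can come from chance alone. The difference between the models in BMDM against MG was past the test for 93 higher and 157 lower genes. Log2 differences were 3.58 for Ch25h, 3.17 for Ly6i, 2.73 for Ctsl, 2.38 for Sgk1, 2.14 for Tmem51, 2.04 for Nrp2, 1.94 for Abcg3, and 1.90 for Cd14. Among lower genes they were −5.39 for Epcam, −5.05 for L1cam, −5.01 for Kit, −5.01 for Ly75, −4.64 for Siglecg, −4.60 for Tgtp1, −4.54 for S100a6 and −4.52 for Lrrk2. The tumour response differed between lineages for 3972 higher and 3330 lower genes, with log2 differences of 9.17 for Spsb1, 8.91 for Rgs1, 8.79 for X99384, 8.55 for C1qa, and 8.42 for Hbegf, and among lower genes −13.80 for Lcn2, −13.07 for S100a8, −11.99 for Xist, −11.92 for Lrg1 and −11.80 for Tubb1. Xist separates the sexes, and Lcn2 and S100a8 are neutrophil genes. The contrast holds these and other differences between monocytes and BMDM, so it does not measure the tumour alone.

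Counts of calls were tested against other splits of the same libraries. In each comparison 1 split, the real one, gave as many calls. Of 56 splits, the highest other gave 2802 calls against 8800 for GEMM BMDM against monocytes, 3453 against 9672 for GL261 BMDM and 3481 against 9644 for monocytes against normal MG. Of 60 splits it gave 788 against 7302 for the tumour response. In these 4 comparisons the share was 1 of 56 or 1 of 60, the smallest possible. It was not adjusted over the comparisons. The other splits mix the groups, which widens the spread within them, and most called 0 genes. A low share was thus likely beforehand, so the test does not exclude chance. The remaining comparisons have 10 splits, too few for a share under 0.05: real and highest other counts were 3194 and 0 (GEMM BMDM against MG), 2692 and 61 (GL261 BMDM against MG), 250 and 0 (their difference), 6731 and 1 (GEMM MG against normal MG), 8879 and 1 (GL261 MG), 5275 and 0 (GL261 against GEMM MG) and 3027 and 3 (GL261 against GEMM BMDM). For GL261 BMDM against MG, the 4 splits that part all 3 pairs include the real one and gave 0 otherwise, as did those of GEMM, and the splits that part 1 pair gave up to 61.

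In 55 genes at 10 CPM or more on average in GL261 MG and under 1 CPM in every library outside GL261, such as Krt8, Col9a1 and H19, counts made up 0.113%, 0.2004% and 0.324% of GL261 MG and 0.0385%, 0.0983% and 0.0784% of GL261 BMDM libraries. RNA of glioma cells could account for them, since 1 source keeps its genes in 1 ratio and the median absolute deviation of the log2 MG to BMDM ratio was at most 0.337 in the 3 tumours (0.297, 0.269 and 0.337). Any other single source, MG included, would also keep 1 ratio, and the deviation was not taken for other gene sets. The test therefore does not identify glioma cells as the source. The CD45 and CD11b gate would remove glioma cells, so free or ingested RNA stays a hypothesis. In GL261 MG 80769, microglia identity genes lay below the other 2 GL261 MG libraries by a median log2 of −1.87 and genes of all leukocytes by −0.93, a difference of −0.93 (bootstrap −1.30 to −0.31) that leaves glioma RNA undecided. The share of BMDM in that sort was bounded at 10.01%, a low quantile of the MG to BMDM ratio over 190 genes of monocytes. Those ratios had a lowest value of 0.0418% and a median of 28.9%. The fall needs 72.6%, so BMDM with the mean profile of the sorted BMDM are excluded as the whole cause. A subset of BMDM with another profile was not tested.

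Arg1 was high in both MG and BMDM of tumour BB30101 (1032 and 1997 CPM) and of 80769 (2790 and 6265.0 CPM). BMDM in the MG sort might raise it. In BB30101 the MG to BMDM ratio of Arg1 was 51.7%, against a bound of 5.98% on their share and a median of 15.2% over genes of monocytes. In 80769 it was 44.5%, against a bound of 10.01% and a median of 28.9%. Itga4, a BMDM gene, had a ratio of 42.1% in 80769 and 8.56% in BB30101. The bounds exclude BMDM with the mean profile of the sorted BMDM as the whole cause. They do not exclude a subset of BMDM high in Arg1. For Chi3l3 in 80769 (4421 and 22717 CPM) the ratio of 19.5% against 10.01% is undecided, being under 2 times the bound. A signal in the tumour that acts on both lineages stays open and was not tested.

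Neutrophil markers were higher in monocyte libraries 64817, 64818 and 64819 than in 64820 and 64821 for 11 of 11 markers, by a median log2 of 4.10 (range 1.13 to 6.70), with the largest differences in Ltf, Ngp and Camp. S100a8, of high level in both, was at 2658, 4240.2 and 4637 against 494 and 388 CPM, and 6 of the 11 were at 10 CPM or more in both 64820 and 64821. Neutrophil RNA in the monocyte sort may be the source, but the 11 of 11 only restates the pattern and leaves this open, and the labels describe no gate for the blood. Rn45s taking counts from the other genes of 64820 and 64821 is excluded, since its 13.5% and 14.3% of their counts lower every other gene alike, by less than log2 0.3. No biological explanation was tested.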

How the results depend on the processing

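The alternatives that leave out tumour 80769 or monocyte libraries were chosen after seeing the data, and the others before. No called list or called named gene result reversed under the alternatives run on it, and leaving out those libraries moved no count by more than 1.5 times. Of the lists not called, microglia identity in the difference of the models was lower without the replicate block and higher with it (camera adjusted p = 0.814 and 0.788). Named genes that were not called changed sign under some alternatives, as Ly6c1 did in GL261 BMDM against MG with the block. Among all called genes, 3 reversed in GL261 BMDM against monocytes and 1 in GL261 against GEMM BMDM without tumour 80769, 1 in monocytes against normal MG without 64817, 64818 and 64819, and 2 in GL261 BMDM against monocytes without its library 80769. Which direction held more calls turned under at least 1 alternative in 8 of 11 comparisons, and in none for GEMM and GL261 BMDM against MG and GL261 BMDM against monocytes, so the balance of higher and lower calls is not a stable result. The counts for tumour against normal cells and monocytes against normal MG, and the overlaps of tumour against normal comparisons, stayed within 1.5 times under every alternative run. Where a count moved, the cause was not tested unless stated. Monocyte libraries were the shallowest, yet simulated edgeR recovery of 2-fold and 4-fold changes was highest for GEMM BMDM against monocytes (52% and 89%). It was lowest for the interaction of the models (15% and 65%). Groups of 3 alone do not account for that, since GEMM BMDM against MG gave 40% and 85%.

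With DESeq2, GEMM BMDM against MG had 1900 genes lower, GL261 BMDM against MG 1768 lower, their difference 366 higher and 428 lower, the lower genes shared by both models 827 and the lower genes kept from monocytes against normal MG 670. With limma-voom the same were 2038, 1857, 384 and 435, 894 and 769. No filter left 43 genes higher in the difference of the models. With only the groups compared, the fit has fewer samples for the spread. GL261 BMDM against MG then had 599 higher and 234 lower, and the difference 7 and 14. GL261 against GEMM BMDM had 707 lower, shared genes were 400 and 174 and kept genes 325 and 154. It kept 808 of 2553 calls for GL261 BMDM against MG but 2474 of 3078 for GEMM, so fewer samples alone do not account for the loss. The lowest r between libraries of a group was 0.937 in GL261 MG and 0.956 in GL261 BMDM. It was 0.977 and 0.969 in GEMM and 0.987 in normal MG. The main fit shares its spread over all groups, so its p-values for GL261 may be too small. In the fit with the replicate block, GEMM BMDM against MG had 2179 higher and 1496 lower, GL261 1957 and 1246 and their difference 105 and 192, and the pairing moved no count by more than 1.5 times. The calls themselves changed more: the block lost 292 calls in GEMM, 347 in GL261 and 106 of 250 in their difference. With the block 5 lists, given in the report, gained a call, 12 named gene results gained 1 and 14 lost 1, and no other call of a list or named gene changed.

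Leaving out 1 library at a time, the difference of the models ranged from 33 to 280 higher and from 49 to 213 lower. GEMM BMDM against MG ranged from 1105 to 2211 higher and 722 to 1481 lower, GL261 BMDM against MG from 466 to 1193 lower, and shared lower genes from 324 to 556. Kept lower genes ranged from 281 to 481. GL261 against GEMM MG ranged from 1811 to 2998 higher, and GL261 against GEMM BMDM from 1045 to 1793 higher and 822 to 1805 lower. Of named gene results, leaving out 1 library lost 508 calls, gained 57 and left 20355 alike. Named gene results gained and lost calls with DESeq2 (21 and 1), limma-voom (45 and 29), no filter (1 and 37), the stricter filter (2 and 1) and only the groups compared (3 and 94). DESeq2-type size factors lost 3 and the fit without robust dispersion 1. Without tumour 80769 they gained 17 and lost 21, without monocytes 64820 and 64821 3 and 19, and without monocytes 64817, 64818 and 64819 4 and 25.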

Other observations

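The comparison in this part was planned before the data were seen, its choice for this part was made after, and no explanation was tested.

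Cells sorted as BMDM from GEMM tumours carried transcripts of dendritic cells beside those of macrophages. Flt3, the receptor of a growth factor for dendritic cell progenitors, was higher in GEMM BMDM than in GEMM MG (log2 4.65 ± 0.84, adjusted p = 0.000687), at 189 ± 77.8 against 7.399 ± 7.55 CPM (n = 3 each, edgeR). The described sort parts these groups by a Flt3-Cre reporter, so the direction of Flt3 may follow from the sort and is not independent evidence. Cd209a, a lectin found on dendritic cells derived from monocytes, was also higher (log2 5.16 ± 1.07, adjusted p = 0.00314), at 222 ± 88.7 against 6.07 ± 6.403 CPM. Cd209a is also in the monocyte-derived macrophage list, so it does not single out dendritic cells. Macrophage genes were high in the same libraries, with C1qa at 1710 ± 318 CPM and Mertk at 217 ± 87.2 CPM. Pooled RNA does not tell whether single cells hold both.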
